A study of Homo sapiens with 3 samples.

How the data were processed

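Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on stable HEK293T lines, a human embryonic kidney line that carries the SV40 large T antigen. The lines had been transfected with Myc-tagged wild-type Idax, with a Myc-tagged DNA-binding mutant of Idax, or with an empty vector, and the immunoprecipitation used an anti-c-Myc agarose gel in all 3. Idax, also called CXXC4, is a protein with a CXXC zinc finger, a domain that binds DNA containing unmethylated CpG. Per the labels' protocols, nuclei were isolated, chromatin was sheared on a Covaris instrument, and libraries were made with a TruSeq kit and sequenced on an Illumina HiSeq.

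The design text gives 2 replicates per condition, but each analysed condition had 1 peak list. How the replicates were combined is not given in the sources used here. The submitters' processing notes name Bowtie 0.12.7, MACS 1.4.1 and the human build hg19. The design text describes binding sites detected over the empty-vector cells. The analysed data were thus 2 peak lists, wild type over empty vector and mutant over empty vector. The empty-vector reads themselves were not analysed here. Each list had 5 columns (chromosome, start, end, peak name and score) and no header.

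The score of each peak is the authors' deposited value and was used to describe, rank or filter peaks within a list and, within the wild-type list, to compare peaks of like width. Scores of both lists are given side by side but were not tested against each other. The lowest scores were 50.01 and 50.43 and the highest was 3100. These values have the form of the score that MACS writes, a multiple of the negative logarithm of the p-value, but the lists do not state the scale. The number of reads behind a score is unknown. The score also grows with sequencing depth, so a difference in depth between the libraries would change both the score and the number of peaks. Peak starts were converted from 0-based to 1-based, and every position below is on hg19 as named in the processing notes.

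Numbers of peaks, widths and scores were summarised per list. With 1 list per condition, no test between conditions was possible, and p-values below describe positions of peaks within these lists. Peaks were called overlapping when they shared at least 1 bp. The overlap of the mutant list with the wild-type list was set against 10000 random placements of the mutant peaks, widths kept, on their own chromosomes between the first and the last wild-type peak (one-sided permutation p). Clustering of the mutant list within 10 Mb was set against 10000 placements over all chromosomes, in proportion to span, and against 10000 placements of its chromosome 13 peaks on that chromosome. Clustering of the wild-type list was set against 1000 random placements of each peak on its own chromosome, counted in fixed windows of 1 Mb. Unassembled sequence was not masked, because the hg19 sequence was not used here. Numbers of peaks per chromosome have exact Poisson 95% intervals, and shares have exact Clopper-Pearson 95% intervals. Both cover counting error only. Chromosome length was taken as the span from the first to the last wild-type peak. Correlations over chromosomes are Pearson's r and Spearman's rho with two-sided permutation p from 100000 permutations, and 2 relations were computed in that family.

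The only gene table used was of another assembly, GRCh38.p14. It gave the number of protein-coding genes on each chromosome (20033 on the 24 chromosomes) and the chromosomes of CXXC4 and TET2, and none of its coordinates was used. No peak was assigned to a gene. For this reason 7 results planned before the data were examined were left out: the shares of wild-type and of mutant peaks at promoters, CpG content of the peaks, promoters by CpG class, score against CpG content, the 25 gene lists, and sequence words at peak centres. The rule for named regions, also fixed before the data were examined, was the 10 wild-type peaks of highest score, the 10 mutant peaks of highest score and every mutant peak (up to 10) that overlapped a wild-type peak. Other mutant peaks and windows named below were chosen after their values were seen.

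The overlap and clustering tests were tested on simulated lists of 38 peaks. Of 100 lists placed at random, 3 passed the threshold of 0.05 in the overlap test, and 100 of 100 lists with 10 planted overlaps passed it. In the test for clustering within 10 Mb, 0 of 100 random lists and 100 of 100 lists with 8 peaks planted in one 10 Mb block passed. The simulated lists were placed evenly over the spans, as the tests themselves assume. They check the calculation and not the effect of an uneven background. The alternatives tried were a minimum score of 100, merging of peaks within 1 kb, autosomes and X only, other definitions of overlap and other placements. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.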

Results

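Sites bound by Myc-tagged Idax in HEK293T chromatin were compared with those of a DNA-binding mutant of the same protein, each called over cells with an empty vector. The comparison asks which sites Idax occupies and how many of them remain when its DNA binding is impaired. One peak list per condition was analysed, so the values below have no replicate error, and read depth is unknown.

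The wild-type list held 17089 peaks on all 24 chromosomes, which together covered 21.2 Mb. The mutant list held 38 peaks on 14 chromosomes, 1 of them on Y, which covered 0.0177 Mb. The wild-type list thus held 450 times as many peaks and covered 1197 times as much sequence. Wild-type peaks had a median width of 1116 bp (quartiles 826 and 1503 bp), and mutant peaks had a median width of 288 bp (quartiles 210 and 464 bp). The median score was 223 in the wild-type list (quartiles 109.3 and 407.8) and 55.4 in the mutant list (quartiles 52.86 and 59.36). The highest score was 3100 in the wild-type list and 94.45 in the mutant list. No test between the conditions was possible with 1 list each, and the score is the peak caller's own value and depends on depth. Each construct was in its own stable line, and protein amount and immunoprecipitation yield are not in the lists. The difference in peak number can therefore not be put down to DNA binding alone.

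**Figure D1:**
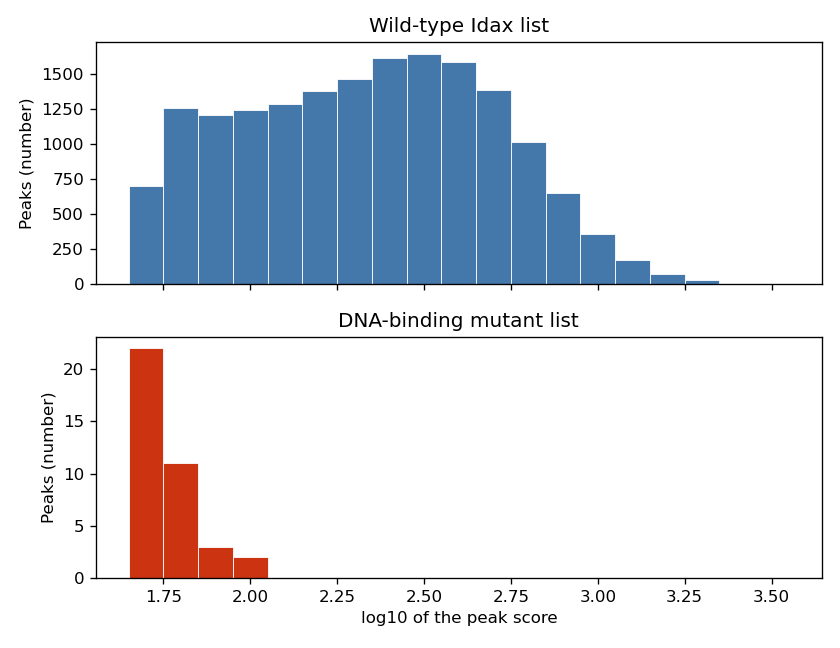
Number of peaks (vertical axes, different scales) by log10 of the peak score (horizontal axis) for the wild-type list (upper panel, 17089 peaks) and the mutant list (lower panel, 38 peaks). Mutant scores end at 94.45, while the wild-type scores run up to 3100.

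The strongest wild-type peak lay on chromosome 10 at 77158243 to 77166306, was 8064 bp wide and had a score of 3100. The next was on chromosome 17 at 79315563 to 79320845, with a score of 2552.23 over 5283 bp. A narrower peak on chromosome 20 at 49347102 to 49348908 scored 2418.6, and a 4358 bp peak on chromosome 9 at 82184754 to 82189111 scored 2407.3. Chromosome 1 held 2 of the 10 strongest peaks, at 28240412 to 28242016 (score 2214.24) and at 117663870 to 117665288 (score 2115.83). A second peak on chromosome 9, at 140134542 to 140136012, scored 2149.59. The remaining 3 were on chromosome 7 at 39988473 to 39991689 (score 2082.23), chromosome 10 at 121631272 to 121633234 (score 2051.81) and chromosome 5 at 98108401 to 98110664 (score 2042.35). None of these 10 regions, which lay on 7 chromosomes, overlapped a mutant peak. Across the wild-type list, stronger peaks were wider, with a Spearman rho of 0.77 across the 17089 peaks, which are not independent replicates. The median width was 714 bp among the 4274 peaks of lowest score (up to 109) and 1640 bp among the 4272 of highest score (408 and above).

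Wild-type peaks were unevenly spread over the chromosomes. Chromosome 19 was the most densely occupied, with 1259 peaks or 21.4 per Mb (95% interval 20.2 to 22.6), against 5.7 per Mb over all chromosomes. Chromosome 17 followed with 13.4 per Mb (12.6 to 14.2) and chromosome 22 with 13 per Mb (11.9 to 14.3). The sparsest autosomes were chromosome 18 with 2.82 per Mb (2.45 to 3.21), chromosome 13 with 3.09 per Mb (2.74 to 3.46) and chromosome 4 with 3.17 per Mb (2.93 to 3.44). Over the 24 chromosomes, the number of wild-type peaks rose with the span covered by the list (Pearson r = 0.61, permutation p = 0.0014; Spearman rho = 0.58, permutation p = 0.0031, adjusted p = 0.0031). Without chromosomes 1 and 2, the 2 farthest from the median span, r was 0.43 (permutation p = 0.047).

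The number of wild-type peaks followed the number of protein-coding genes on the chromosome, with r = 0.97 and rho = 0.96 (permutation p = 1e-05 for each, the smallest that the permutations can give, and adjusted p = 2e-05 for rho). This relation was examined after the data were seen. Without chromosomes 1 and Y, r was 0.94 (permutation p = 1e-05). The list held 0.85 peaks per protein-coding gene. Chromosome 10 lay above this with 1.16 peaks per gene (95% interval 1.08 to 1.24), as did chromosome 22 with 1.01 (0.92 to 1.11) and chromosome 6 with 0.98 (0.92 to 1.04). Chromosome 11 lay below it with 0.66 (0.61 to 0.70), as did chromosome X with 0.65 (0.60 to 0.71) and chromosome Y with 0.17 (0.09 to 0.31). Peaks counted on a chromosome were not assigned to its genes. HEK293T has an abnormal copy number, and the copies of each chromosome were not taken into account.

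**Figure D2:**
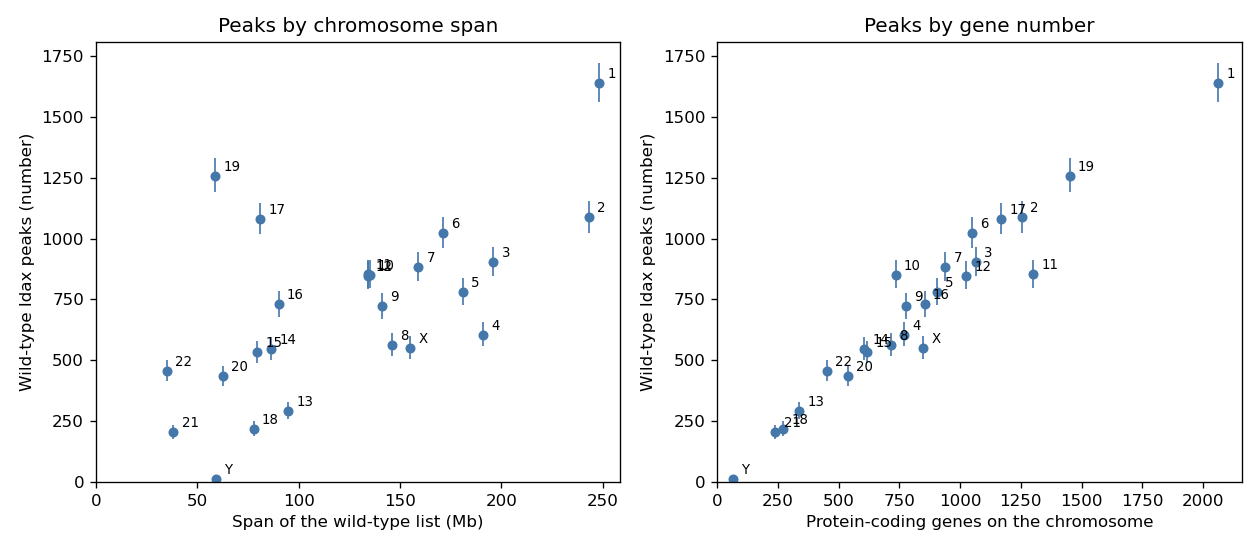
Number of wild-type Idax peaks per chromosome (vertical axes) against the span of the list on that chromosome in Mb (left) and against its number of protein-coding genes (right). Points are chromosomes, labelled by name, and bars are exact Poisson 95% intervals, smaller than the point where not visible. Chromosomes 17 and 19 stand high for their span, and peak numbers follow gene number with r = 0.97.

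Within chromosomes, wild-type peaks gathered in some regions and were missing from others. Of 3017 windows of 1 Mb, 153 (5.07%) held 20 or more peaks and together contained 4371 peaks (25.6% of the list). Random placement gave a mean of 43.6 such windows and at most 58 (permutation p = 0.001, the smallest that 1000 placements can give). The densest window, on chromosome 19 from 1000001 to 2000000, held 69 peaks, and the densest random window held at most 42. The next densest were on chromosome 19 from 49000001 to 50000000 with 57 peaks and on chromosome 6 from 28000001 to 29000000 with 54 peaks. The block of 3 adjoining windows on chromosome 6 from 26000001 to 29000000 held 148 peaks, or 49.3 per Mb, with a median score of 188. Windows without a peak numbered 662 (21.9%), against a mean of 92.4 at random placement (permutation p = 0.001). That count includes unassembled sequence such as centromeres, where no peak can be called. Neighbouring peaks less than 1 kb apart numbered 1327, against a mean of 277 at random placement (permutation p = 0.001).

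Peaks on chromosome X had a lower median score than those on the autosomes. The median score was 173 over 550 peaks on X and 225 over 16528 autosomal peaks, a difference of -52.5. This comparison was chosen after the data were seen, and no p-value is given for it. Each of the 22 autosomes had a higher median score than X. Copy number was not taken into account here either. Chromosome Y held 11 wild-type peaks with a median score of 162. Of these, 7 may come from reads shared with chromosome X, as described below.

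The 38 mutant peaks were not spread like the wild-type peaks. Chromosome 13 held 14 of them (36.8%, 95% interval 21.8 to 54), whereas it made up 3.17% of the span and held 293 wild-type peaks (1.71%). No other chromosome had more than 5 mutant peaks, and 10 chromosomes had none. The 14 peaks lay between 62342143 and 92942834, a block of 30.6 Mb in which the wild-type list had 33 peaks (1.08 per Mb, against 3.09 per Mb over chromosome 13). From 62342143 onwards, 9 mutant peaks began within 10 Mb, and 10000 random placements of the 38 peaks over all chromosomes never gave more than 5 in any 10 Mb (permutation p = 0.0001, the smallest they can give). That test includes the excess on chromosome 13 itself. With 14 peaks placed at random on chromosome 13 alone, the mean of the highest number in 10 Mb was 4.24, and 1 of 10000 placements reached 9 or more (permutation p = 0.0002). The tests on chromosome 13 were chosen after the data were seen. Of these 14 peaks, 1 overlapped a wild-type peak (7.14%, 95% interval 0.181 to 33.9), against 9 of the 24 elsewhere (37.5%, 18.8 to 59.4). This difference did not pass Fisher's exact test (two-sided p = 0.059).

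**Figure D3:**
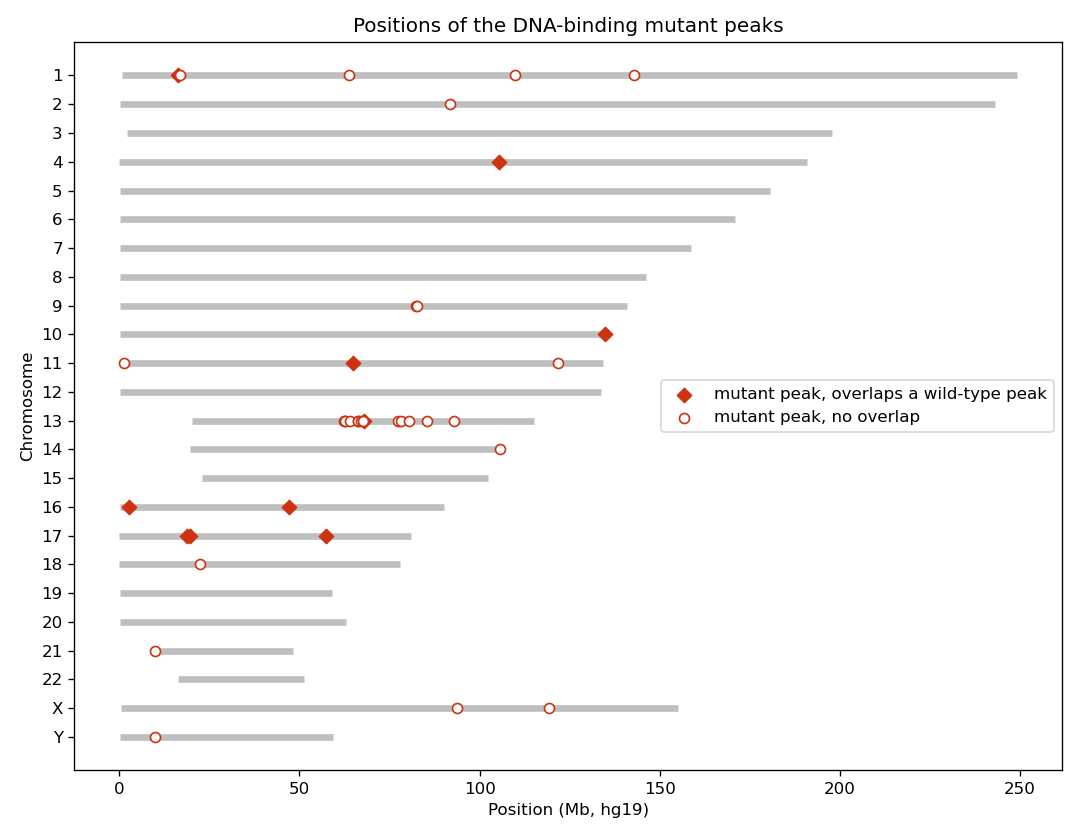
Positions of the 38 mutant peaks (horizontal axis, Mb on hg19) on each chromosome (vertical axis). Grey bars are the span from the first to the last wild-type peak, filled diamonds are the 10 mutant peaks that overlap a wild-type peak, and open circles are the other 28. Chromosome 13 holds 14 mutant peaks.

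**Figure D4:**
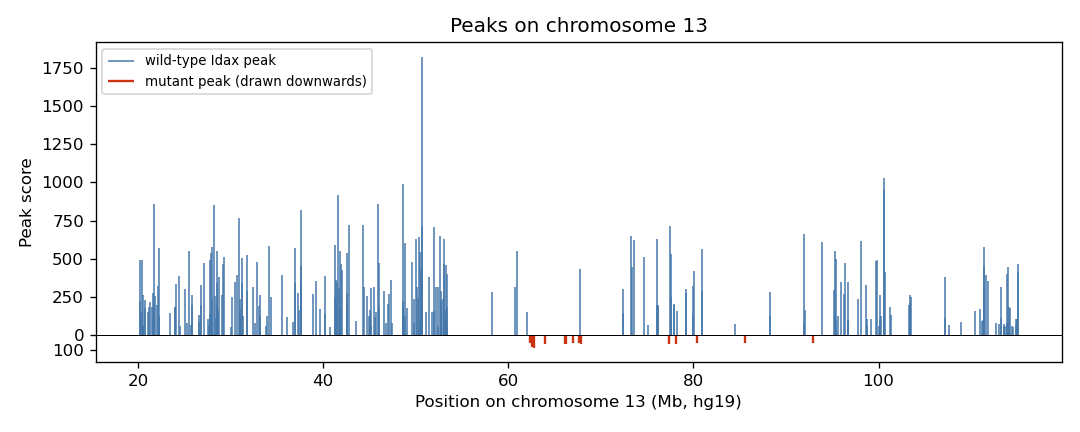
Peak scores (vertical axis) along chromosome 13 (horizontal axis, Mb on hg19), with the 293 wild-type peaks drawn upwards and the 14 mutant peaks drawn downwards on the same scale. The mutant peaks lie between 62342143 and 92942834, where the wild-type list averages 1.08 peaks per Mb, though 3 of them, between 77397016 and 80405044, have 3 or 4 wild-type peaks within 500 kb.

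Of the 38 mutant peaks, 10 overlapped a wild-type peak (26.3%, 95% interval 13.4 to 43.1), which is 0.0585% of the wild-type list. Random placement gave a mean of 0.33 overlaps and at most 4 (the observed number was 30.5 times the mean, one-sided permutation p = 0.0001, the smallest that 10000 placements can give). Both lists were called over the same empty-vector cells, so part of this excess may come from the shared control. The wild-type peaks at these 10 places had scores from 227 to 950 (median 414), and the highest-ranked of them was number 500 in the wild-type list. Of the 10 mutant peaks, 9 lay wholly inside the wild-type peak.

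The strongest mutant peak, on chromosome 11 at 64863383 to 64863716, scored 94.45 and lay inside a wild-type peak of score 457.47. The next, on chromosome 4 at 105411910 to 105412349, scored 93.09 and lay inside a wild-type peak of score 241.28. This peak may come from reads of the transfected sequence, as described below, and the overlap was not counted without it. On chromosome 17, mutant peaks at 18684357 to 18684678 (score 68.8) and 57287236 to 57287455 (score 67.72) lay inside wild-type peaks of scores 272.42 and 226.58. Another on that chromosome, at 19551091 to 19551596 (score 59.05), shared 467 bp with a wild-type peak of score 527.33. The other 5 overlapping mutant peaks scored lower. They lay on chromosome 1 at 16176336 to 16176533 (score 51.16), chromosome 10 at 134778800 to 134778998 (score 54.62), chromosome 13 at 67804741 to 67805641 (score 54.53) and chromosome 16 at 2732274 to 2732542 (score 53.1) and 47007459 to 47007668 (score 53.97).

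The other 6 of the 10 strongest mutant peaks had no overlapping wild-type peak. Those on chromosome 13 were at 62742113 to 62745511 (score 80.8, 3399 bp wide), at 62604887 to 62606247 (score 75.56, 1361 bp wide) and at 66148235 to 66148731 (score 59.59). The nearest wild-type peaks to them were 752419, 615193 and 1654909 bp away. A peak on chromosome 21 at 9825438 to 9826639 scored 75.26, one on chromosome X at 119266497 to 119266804 scored 63.51, and one on chromosome 14 at 105628802 to 105629032 scored 59.46. Their nearest wild-type peaks were 54869, 111387 and 4388 bp away. Mutant peaks on chromosome 13 had a median width of 424 bp and those elsewhere of 232 bp, a split chosen after the data were seen and given without a test.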

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

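With 1 peak list per condition no replicate could be left out. No paired analysis was possible because each condition had a single list without replicate numbers. At a minimum score of 100 the mutant list held 0 peaks, while the wild-type list held 13319 (77.9%). The overlap of the lists therefore has no value at that setting. The other 17 of 18 alternatives kept the direction and the side of the threshold of the result they bear on, or stayed within 1.5 times its count. Wild-type peaks numbered 15762 after merging within 1 kb and 17078 on the autosomes and X, where the mutant list had 37. The overlap was 10 of 38 when at least 50% of the mutant peak had to be covered, within 1 kb, with placement over all chromosomes, and, chosen after seeing the data, with wild-type peaks of score 100 or more or placement within 250 kb. It was 9 of 24 without chromosome 13, also chosen after seeing the data (permutation p = 0.0001 in each). A change of placement alters only the random expectation, not the observed overlap. The score filter could not lower the overlap either, since the overlapped wild-type peaks scored 227 or more. Nor could a limit of 1 kb, and the rule of 50% had little room, since 9 of the 10 lay wholly inside a wild-type peak. Leaving out Y removed too few peaks to move either count. The 17 also include the relation with gene number, which is a different measure and not another setting of the relation with span. The rho of wild-type peaks with span was 0.57 at score 100 or more and 0.56 without Y. The median score on X was also lower among peaks of score 100 or more (median difference -37.7), a comparison chosen after seeing the data. Settings foreseen before the data were examined for promoter windows, transcription start sites, CpG measures, gene lists and sequence words were not run, since no hg19 sequence or annotation was used here. Read depth is unknown, and all mutant peaks scored between 50.43 and 94.45, so how far their number depends on depth was not tested.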

Other observations

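The tests on chromosomes 13, 4 and Y below were chosen after the result was seen. The test of local placement and the test of width-matched scores were also added after the lists and their overlap had been seen, but before the outcome of either test was known.

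Wild-type peaks on chromosome Y mirrored peaks on chromosome X. Of the 11 Y peaks, 7 had an X peak at one constant shift of 50 kb, whereas no shift more than 5 kb from it, out to 150 kb either way, paired more than 2. The first pair was at 297483 to 298461 on Y (score 291.71) and 347351 to 348463 on X (score 322.09). The last was at 2558826 to 2560031 on Y (score 145.36) and 2608899 to 2610010 on X (score 134.59). The ratio of the Y score to the X score ran from 0.65 to 1.13 with a median of 0.91. The 7 paired peaks are consistent with reads shared between near-identical sequence of X and Y, placed on both copies when aligned to a reference that holds both. The other 4 Y peaks had no partner at this shift. Shifts beyond 150 kb were not tried, so the same source is not excluded for them. No biological explanation was tested.

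For the block of mutant peaks on chromosome 13, the tests argued against random placement over the genome (permutation p = 0.0001) and, given 14 peaks on the chromosome, over chromosome 13 (permutation p = 0.0002). Residual binding at wild-type sites is also argued against as its main source, since 1 of these 14 peaks overlapped a wild-type peak (7.14%, upper 95% limit 33.9%). That limit treats the peaks as independent, though many of them lie close together. Of the 14, 8 had no wild-type peak within 500 kb. A candidate explanation is a difference in DNA copy number between the mutant line and the empty-vector line, which would raise the signal of a long block at many places. The 30.6 Mb of the block do not test this, since they are only the distance from the first to the last of these peaks. Within it, 9 of the 14 lay between 62342143 and 67805641, and the next began at 77397016. Read coverage would be needed to decide. Binding specific to the mutant protein cannot be told apart from it, because each construct was carried by its own stable line.

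The overlap of 10 mutant peaks with wild-type peaks exceeded that of placement within 250 kb of each mutant peak (mean 0.52, permutation p = 0.0001). This argues against 2 lists that merely favour the same regions at that scale. The placement cannot test a shared preference for stretches as narrow as a peak. If the mutant kept some binding in proportion to the wild-type protein, the shared sites might be strong wild-type sites. All 10 scored above the median of the wild-type list (223). Their median score was 414, against 225 (95% of draws 105 to 425) for wild-type peaks drawn at random. This difference did not pass the test (two-sided permutation p = 0.06 from 10000 draws, chosen after the scores were seen). Medians of 10 draws varied widely, so the failed test does not show that the shared sites resemble random wild-type peaks. That all 10 lay above the list median was not itself tested. Draws in proportion to width, also not foreseen, gave a median of 305 (150 to 536; two-sided permutation p = 0.32). Against wild-type peaks of like width the median was 303 (180 to 474; two-sided permutation p = 0.19), but width and score rise together (rho = 0.77), so this matching removes part of the difference it is meant to test. Residual binding, a signal of the empty-vector control shared by both lists, and signal of the tagged lines unrelated to DNA binding all stay open.

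One shared site would be worth inspecting first. The mutant list had 1 peak on chromosome 4, at 105411910 to 105412349, and only 1 mutant peak scored higher than its 93.09. Chromosome 4 carries CXXC4, the gene of Idax, and also TET2. A transfected coding sequence is present in both Idax lines but not in the empty-vector line, so a candidate explanation is reads from the transfected IDAX sequence counted at the gene of origin in both lists. Whether this peak lies in an exon of CXXC4 was not analysed here, since that needs an hg19 annotation, and the hypothesis stays open.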
